A study of Homo sapiens with 47 samples.

How the data were processed

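The series holds 47 samples of the melanoma cell lines 451Lu and WM983B, of which 32 had a processed file of their own that was used here. These were 20 ATAC-seq libraries, which mark open chromatin by where the transposase Tn5 cuts, 4 ChIP-seq libraries for H3K27ac, a histone mark of active promoters and enhancers, and 8 ChIP-seq libraries for H3K9me3, a mark of heterochromatin. The labels put each library in a group by cell line, by drug response (parental or resistant to the BRAF inhibitor vemurafenib) or by genetic change, and number the replicates. Nothing in the labels says that replicates came from separate cultures, so the spread between them may be technical. The other 15 samples (4 H3K27ac, 4 RNA and 7 input libraries) were not analysed here by themselves.

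The submitters' processing notes name Bowtie2, Picard, MACS2, SICER, STAR 2.5.3 and deepTools and the genome build hg19, without a role or an order. Which tool made which file, read trimming, removal of duplicates and any shift of ATAC-seq reads for the Tn5 offset are not given in the sources used here. The ATAC-seq and H3K27ac files list the peaks of 1 library each, with a score per peak that the authors' peak caller gave, per the deposited files. The smallest scores lay just above 2.00 in 451Lu ATAC-seq, at 1.30 to 1.32 in WM983B ATAC-seq and at 1.39 to 1.89 in H3K27ac. By these scores the ATAC-seq lists of the 2 cell lines did not appear to share a threshold. The H3K27ac lists of parental and resistant cells differed in smallest score within either line. Whether their thresholds differed is not given. The score is the authors' own value and was used to rank or filter peaks within a list. Within a comparison it also served to name regions, to describe gained, lost and constant regions, and to class regions by control score. The H3K9me3 files list broad islands per library, and the deposited columns hold the count of ChIP reads, the count of input reads, a p-value, the fold of ChIP over input and a false discovery rate. The fold in these deposited files equalled the ratio of ChIP to input counts times 1 factor per library, within a relative tolerance of 1e-05, in each island with input reads (2 islands had none). The authors listed islands without a limit on the p-value, which reached 1, and every listed island was used.

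A table of 1848 genomic intervals in 451Lu was also deposited by the authors, with columns named as DESeq2 writes them. Its mean normalized count was read as a signal, and the log2 fold change, its standard error, the test score, the p-value and the adjusted p-value are the authors' deposited values. The table names neither the assay nor the libraries behind it, nor which group a positive fold change favours. The adjusted p-values equalled a Benjamini-Hochberg adjustment over all 1848 intervals within the same tolerance. Interval starts and ends lie on a grid of 20 kb, and intervals with equal start and end occur, so the printed end was taken as the start of the last grid step. The 3 intervals on other chromosomes than 1 to 22 and X entered no overlap.

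Peaks and islands on chromosomes 1 to 22 and X were used. For each comparison the lists of all 4 libraries were merged into union regions, and a region was called in a library where at least 1 bp of it was covered. A region was gained when called in both treated and in neither control library, and lost in the reverse case. With 2 libraries against 2, there are 3 splits and the smallest exact two-sided p is 0.333, so an exact permutation of the labels cannot pass 0.05. Regions were either called or not in a library, and no model-based test was fitted to these calls. As background, the same counts were taken for the 2 mixed pairings, each setting 1 library of each group against the others, which gives 4 counts per comparison. Peak lists carry no sequencing depth, which is unknown here. Lists of equal length, the best-scoring peaks of each library up to the shortest list of the comparison, were 1 of the alternatives.

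Overlaps between region sets were tested by circular permutation, 1000 rotations of one set along the regions, two-sided, with Benjamini-Hochberg adjustment over the 8 overlap tests. The smallest p that these rotations can give is 0.001. Odds ratios carry 95% intervals that cover counting error only and treat neighbouring regions as independent. For gains shared by 2 comparisons, the regions entering the odds ratio were those called in none of the 4 control libraries. A region enters only if some library called it, which lowers the odds ratio by construction. The share of regions changed in one direction among those changed in both comparisons, with an exact 95% binomial interval, was added after the data were seen. Beside it stands the share that unrelated changes would give, computed as if the changes of the 2 comparisons were independent among regions with the same calls in the 4 control libraries. Also added then were odds ratios of losses among regions called in all 4 controls, and of gains among regions called by at least 1 ATAC-seq library outside the 2 comparisons and by no control, combined by the Mantel-Haenszel method within classes. H3K9me3 was also counted base by base, a base being lost or gained by the same rule as a region. Intervals of the authors' table were compared for the presence of a feature by two-sided Fisher's exact tests, adjusted over 24 tests. A feature was placed in an interval by its centre.

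The replicate numbers of the labels gave no pairing in 451Lu: the correlation over regions of the replicate differences in treated and control libraries lay between -0.00973 and 0.000623 in 6 comparisons. It was 0.252 in WM983B ATAC-seq. After the data were seen, the labels of the ATAC-seq libraries were therefore set against H3K27ac, by the odds ratio of resistant-only against parental-only H3K27ac at the regions of each side of a split. Libraries were kept in the groups that the labels give. The calling rule uses both libraries of a group alike, so a block for the number changes no count.

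The region counting was tested on lists simulated from the 82621 peaks of parental 451Lu ATAC-seq replicate 1, with peaks missed at random in each list. Of 2000 planted gains 1805 were recovered among 1962 gained regions, and of 1000 planted losses 906 were recovered among 1078 lost regions. Peaks were missed without regard to score. The mixed pairings of the real 451Lu resistant and parental libraries gave 709 to 1328 regions, so their replicates differed more than the simulated lists. The recovery therefore tests the counting and does not give error rates for the data. The rotation test was tried on random clustered labels rather than on peak lists. Of 200 unrelated pairs of such label sets, 7 gave a rotation p under 0.05. These sets lacked the rule that a region enters only if called, so the rate does not cover the effect of that rule.

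Regions were named by a rule fixed before the data were examined. It takes, for each ATAC-seq comparison, the 2 gained and 2 lost regions with the largest smaller score of the libraries holding them, and for H3K9me3 the 2 longest gained and 2 longest lost. In the authors' table it takes the 10 largest positive and 10 largest negative fold changes with adjusted p under 0.05 and a mean count of at least 100. The coordinates are those of hg19. The reference given held gene tables of GRCh38 and no hg19 sequence or annotation, so no region was assigned to a gene, exon, intron or UTR. The planned AP-1 motif test, the 18 gene lists with their markers of other cell types, the single genes named by the rule, and promoter-only distances were not run for the same reason, and the RNA test was replaced by the interval table. Alternatives tried were a call needing 50% of the region covered, the better-scoring 50% of each list, lists of equal length, neighbours merged within 500 bp (5000 bp for H3K9me3), leaving out each replicate, and stricter thresholds in the table. Alternatives added after the data were seen were islands with a false discovery rate under 0.01 and a fold above 1, odds ratios over the regions of all 20 ATAC-seq libraries, the interval end as printed, 5 classes of interval length, and WM983B counts within each replicate number. The ranking of resistant gains into 10 groups was also added then. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.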

Results

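The series profiled chromatin in 451Lu and WM983B melanoma cells that were sensitive to the BRAF inhibitor vemurafenib (parental) or had been made resistant to it. It also profiled 451Lu cells that over-express the AP-1 transcription factor subunits c-JUN and c-FOS (AP1), carry a short hairpin RNA against p150 (shp150), or carry both (shp150_AP1). Their controls were a vector, an NT control and the combination of these (vector_NT). Each ATAC-seq and H3K9me3 group had 2 libraries with a file. Each H3K27ac group had 2 libraries by the labels, of which 1 had a file used here. The 451Lu ATAC-seq lists held 82913 ± 412 peaks in parental (SD, n = 2) and 92236 ± 3272 in resistant cells (SD, n = 2), covering 45.9 ± 0.470 Mb and 49.0 ± 1.90 Mb. The shp150_AP1 and vector_NT lists were of similar length, at 86437 ± 2889 and 82195 ± 3569 peaks (SD, n = 2). The single-change lists were shorter, with 53017 ± 3992 peaks in AP1, 55420 ± 1988 in vector, 43406 ± 718 in shp150 and 54515 ± 1548 in NT cells (SD, n = 2). WM983B lists held 138868 ± 13210 parental and 138725 ± 8777 resistant peaks (SD, n = 2). H3K9me3 islands numbered 66522 ± 6372 in parental, 45212 ± 7207 in resistant, 56131 ± 10351 in shp150_AP1 and 72137 ± 6882 in vector_NT cells (SD, n = 2). ChIP reads inside the islands ranged from 11.5 M (shp150_AP1 replicate 1) to 31.1 M (vector_NT replicate 1), while the peak lists give no depth.

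The first comparison asked where chromatin opened or closed as 451Lu cells became resistant. Of 114302 regions, 11191 (9.79%) were gained in resistant cells, covering 4.80 Mb, and 4527 (3.96%) were lost, covering 1.78 Mb, while 62104 were called in all 4 libraries. The mixed pairings of the same libraries gave 709 to 1328 regions, so gains exceeded the highest mixed count 8.43-fold and losses 3.41-fold. The best-scoring gains lay at chromosome 17, 73689573 to 73690198, with peak scores of 51.7 and 42.2 in the resistant libraries, and at chromosome 8, 61966596 to 61967364, with 40.2 and 42.4. The best-scoring losses lay at chromosome 16, 77417595 to 77418187, with parental scores of 29.2 and 26.0, and at chromosome 4, 186693376 to 186693795, with 25.4 and 26.1. Gained regions were narrower than those called in all 4 libraries (median 406 bp against 681 bp) and had lower median scores (6.52 against 17.5). With lists of equal length 8200 regions were gained and 6581 lost, and the ratio of gains to losses was 1.25 in place of 2.47.

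**Figure D1:**
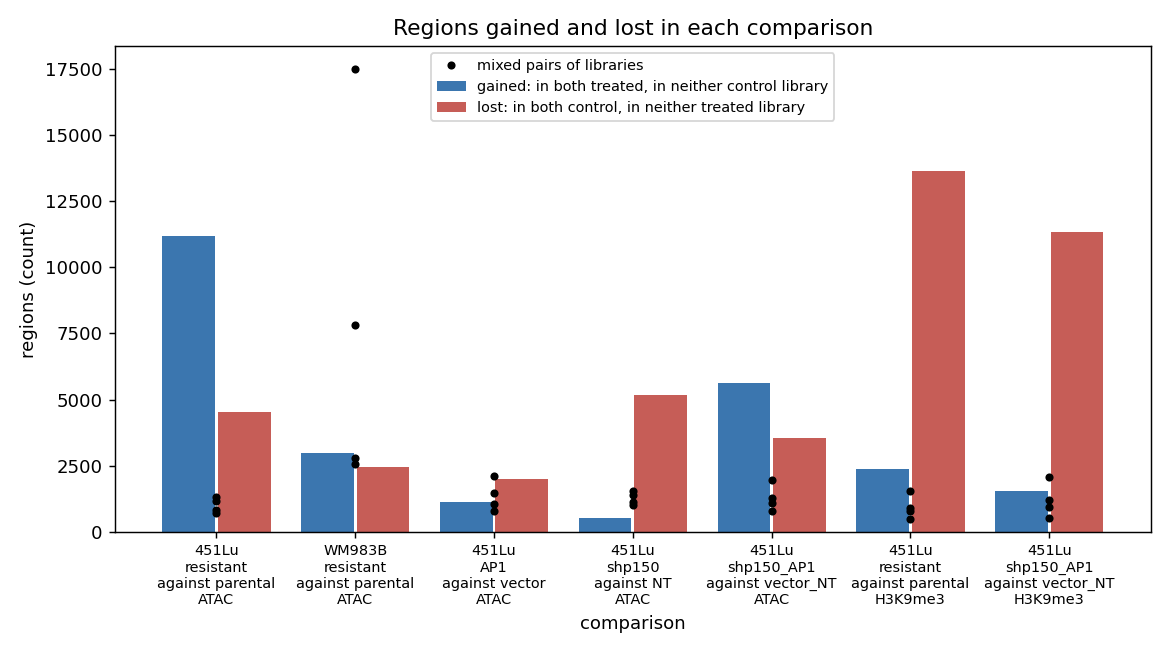
Bars count the regions gained (blue) and lost (red) in each comparison on a linear axis, and black points give the 4 counts from the mixed pairings of the same libraries. Bars for 451Lu resistant ATAC-seq stand at 11191 and 4527 against mixed counts of 709 to 1328, while in WM983B, grouped by label, the mixed counts reach 17485.

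In WM983B the counts between libraries labelled resistant and parental did not stand out from the mixed pairings. The libraries labelled resistant gained 2963 and lost 2460 of 201296 regions, but a split by replicate number gave 7798 and 17485, and the crossed split 2806 and 2574. The best-scoring gain lay at chromosome 10, 97002836 to 97003035 (scores 10.1 and 13.8), followed by chromosome 11, 6337175 to 6337291 (9.94 and 11.5). The best-scoring losses lay at chromosome 6, 5379955 to 5380144 (10.3 and 11.5), and at chromosome 10, 102774171 to 102774269 (8.04 and 10.6). The base overlap (Jaccard index) was 0.578 and 0.609 between parental and resistant libraries of the same number, above the 0.510 between the parental and the 0.509 between the resistant replicates. Within replicate 1, 31822 regions were called only in resistant and 28466 only in parental cells. Within replicate 2 these were 30881 and 29618. Of 245 regions that changed in both cell lines, 48.6% (exact 95% interval 42.2 to 55.0%) changed in one direction, where unrelated changes at the same control calls would give 35.8%. H3K27ac, from other libraries that both carry number 2, went with the replicate numbers and not with the ATAC-seq labels. The odds ratio of resistant-only against parental-only H3K27ac was 30.2 (95% counting interval 19.1 to 47.8) at regions open only in replicates 2 against only in replicates 1, and 1.26 (0.606 to 2.61) at regions gained against lost by label. In 451Lu these ratios were 0.357 (0.0624 to 2.05) and 161 (69.1 to 373). Each WM983B ATAC-seq value by group therefore rests on labels that H3K27ac did not follow.

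Over-expression of c-JUN and c-FOS alone was compared with the vector. AP1 cells gained 1116 and lost 1994 of 69797 regions, and the mixed pairings gave 769 to 2119, so neither count exceeded the highest of them. Lists of equal length gave 1397 gained and 1544 lost, both above the highest mixed count of 1321. The region at chromosome 1, 59248012 to 59248601, was among the best-scoring gains (scores 18.8 and 11.6), next to chromosome 13, 20994005 to 20994346 (14.4 and 13.3). The best-scoring losses lay at chromosome 17, 15356614 to 15357004 (17.0 and 17.2), and at chromosome 2, 83952879 to 83953251 (13.5 and 13.4). The chromosome 1 site was also the best-scoring gain of shp150_AP1 cells. Only 2 regions were called in all 4 libraries with over-expressed c-JUN and c-FOS and in none of the 12 other 451Lu ATAC-seq libraries. They were this site, at 59247944 to 59248697 in the union, and a weaker one at chromosome 14, 51421618 to 51421971, with a smallest score of 3.25. This search was chosen after the values were seen. Reads from an over-expressed construct can be listed as a peak at the native gene it copies, and since no region was assigned to a gene, it was not tested whether these regions were open chromatin or construct reads.

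The hairpin against p150 alone, compared with NT, went with fewer open regions: 5185 of 69032 were lost and 516 gained, against 1009 to 1546 in the mixed pairings. The best-scoring losses both lay on chromosome 22, at 30721161 to 30721519 (scores 18.6 and 17.9) and at 20881089 to 20881475 (14.7 and 14.8). The best-scoring gains both lay on chromosome 2, at 156022113 to 156022527 (10.96 and 13.7) and at 149584384 to 149584683 (9.07 and 10.4). The shp150 lists were also shorter than the NT lists. Lists of equal length gave 2035 lost and 1356 gained regions against at most 1327 in the mixed pairings.

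On the full lists, the combined cells, set against vector_NT, gained more regions than either single change, while the hairpin alone lost more. In the combined cells, of 108325 regions 5624 (5.19%) were gained and 3534 (3.26%) lost, 2.89-fold and 1.82-fold above the highest mixed count of 1943. The hairpin alone lost 5185 regions (7.51%), 3.35-fold its own highest mixed count. Besides the chromosome 1 site (scores 26.4 and 26.6), to which the same limit applies, the best-scoring gain lay at chromosome 5, 167126501 to 167126947 (26.1 and 23.01). The best-scoring losses lay at chromosome 2, 32500808 to 32501218 (26.3 and 24.8), and at chromosome 10, 16627124 to 16627494 (20.1 and 22.4). Because the single-change libraries had shorter lists, the difference in counts between the combined and the single changes was not tested.

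The engineered cells were then compared with the resistant cells, to see whether the same regions had changed. Resistant and shp150_AP1 cells shared 1773 gains and 829 losses, while 90 regions were gained in resistant and lost in shp150_AP1 cells and 78 the reverse. Thus 93.9% of the 2770 regions changed in both (exact 95% interval 93.0 to 94.8%) changed in one direction. The control calls set the direction of such a region, and parental and vector_NT libraries were alike (Jaccard index 0.713 to 0.719). Unrelated changes at the same control calls would give 75.8% over the regions of these 8 libraries and 46.9% over those of all 20, so the share alone does not measure a common effect. The shared gains were 15.9% of the resistant gains and the shared losses 18.5% of the resistant losses. Among 26530 regions called in no control library, the odds ratio of the gains was 2.01 (95% counting interval 1.88 to 2.16, circular permutation p = 0.001, adjusted p = 0.00133). The ratio was 12.7 over the regions of all 20 ATAC-seq libraries. It was below 1 without resistant replicate 1 (0.791), resistant replicate 2 (0.726), shp150_AP1 replicate 1 (0.750) or shp150_AP1 replicate 2 (0.698). Leaving out a treated library removes most regions gained in neither comparison, which lowers this ratio by construction. Those values therefore do not show a reversal. Without each control library in turn the ratio was 2.06 to 2.18. Tests that hold the control calls fixed were added after the data were seen. Among regions called in all 4 control libraries, 829 were lost in both comparisons, 1487 in resistant and 1188 in shp150_AP1 cells only (odds ratio 28.5, 95% counting interval 25.8 to 31.6; 9.36, 8.41 to 10.4, within chromosome and 5 classes of control score). Over 99180 regions called by another library and by no control, the odds ratio of the gains was 10.98 (10.05 to 11.99) within the number of other libraries calling the region, and 9.06 to 11.1 without each library in turn.

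The best-scoring resistant gains were the most often open in shp150_AP1 cells. The resistant gains were ranked by score and divided into 10 equal groups. In the group with the highest scores, 59.6% of 1119 regions (exact 95% interval 56.7 to 62.5%) were called in both shp150_AP1 libraries, and 8.40% in both vector_NT libraries. In the lowest-scoring group these shares were 15.4% (13.3 to 17.6%) and 6.61%. Conversely, 51.2% of the 5624 shp150_AP1 gains (2877 regions) were called in both resistant libraries and 29.4% in neither. The 2877 also count regions that a parental library called, while 1773 regions were gained in both comparisons. The share called in the parental libraries was not taken.

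**Figure D2:**
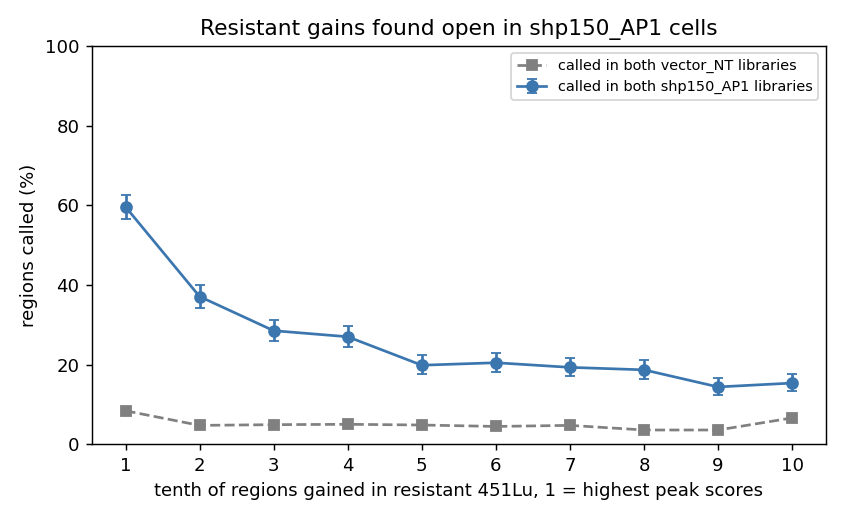
The x axis orders the regions gained in resistant 451Lu into 10 equal groups by peak score, and the y axis gives the percent called in both shp150_AP1 libraries (blue, bars are exact 95% binomial intervals) or both vector_NT libraries (grey). The blue points fall from 59.6% to 15.4% while the grey points stay at 8.40% or below.

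The single changes were compared with the resistant cells in the same way. Of 265 regions changed in both resistant and AP1 cells, 51.3% (45.1 to 57.5%) changed in one direction, and of 441 changed in both resistant and shp150 cells 41.7% (37.1 to 46.5%). Unrelated changes at the same control calls would give 19.4% and 20.6%. Over the regions changed in both, gain or loss in resistant cells was also set against gain or loss in the engineered cells. The odds ratio was 0.989 (0.602 to 1.63) for AP1 and 0.603 (0.312 to 1.17) for shp150. Both intervals include 1, so by this ratio no common direction was found. It does not hold the control calls fixed. Vector and NT lists were shorter and less like parental ones (Jaccard index 0.517 to 0.550 and 0.434 to 0.480), so these shares are not comparable with the 93.9% above. Losses shared with resistant cells numbered 91 for AP1 (13.2 expected from unrelated changes) and 166 for shp150 (45.2 expected). Shared gains numbered 45 (44.0 expected) and 18 (44.1 expected), where the regions of all 20 libraries gave 8.33 and 8.90 expected gains. Control score was not held fixed for these losses. Over regions called by another library and by no control, the odds ratio of the gains within the number of other libraries was 1.45 (0.905 to 2.31) for AP1 and 0.723 (0.405 to 1.29) for shp150. The interval for AP1 left out 1 without resistant replicate 2 (1.71), parental replicate 2 (1.51), AP1 replicate 1 (1.24) or vector replicate 2 (1.53). That for shp150 did so without parental replicate 2 (0.612), shp150 replicate 1 (0.681) or 2 (0.703) or NT replicate 2 (0.625). The odds ratio of AP1 gains among resistant gains was 1.04 (45 shared regions, circular permutation p = 0.837, also 0.837 after adjustment). It reversed to 0.974 without vector replicate 1 (adjusted permutation p = 0.861). It was 0.0683 and 0.0822 without resistant replicate 1 and 2, 0.438 and 0.448 without AP1 replicate 1 and 2, and 9.57 over the regions of all 20 libraries (adjusted permutation p = 0.00114 each). For shp150 gains it was 0.283 (18 shared regions, circular permutation p = 0.001, adjusted p = 0.00133) and 2.24 over all 20 libraries. It fell to 0.0419 and 0.0425 without resistant replicate 1 and 2 and to 0.144 and 0.162 without shp150 replicate 1 and 2. For gains by label in WM983B it was 0.337 (73 shared regions, circular permutation p = 0.001, adjusted p = 0.00133). It was 0.894 without WM983B parental replicate 2, so its size rests on that library, and 0.192 with 50% of the region covered. Without WM983B resistant replicate 1 and 2 it was 0.0557 and 0.0400. The limit on odds ratios over regions called by the libraries themselves, which lowers them, applies to each of these values. Leaving out a treated library lowers them further by construction. AP1 and shp150_AP1 cells shared 36 gains and 82 losses among 180 regions changed in both (65.6% in one direction, 58.1 to 72.5%, where unrelated changes would give 16.8%).

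H3K27ac was listed in 1 library per group, so its differences have no replicate check. In 451Lu 32300 regions were called only in resistant, 12772 only in parental and 19204 in both cells. In WM983B 13499 were called only in resistant, 27839 only in parental and 22214 in both. The longer list of each line also reached a lower smallest score, 1.44 in resistant against 1.89 in parental 451Lu and 1.39 in parental against 1.81 in resistant WM983B. The list lengths on the chromosomes used were 51710 resistant against 32304 parental peaks in 451Lu, and 36022 against 50336 in WM983B. With lists of equal length the resistant-only and parental-only counts were 16020 and 15803 in 451Lu and 15858 and 15972 in WM983B. With 1 list on each side, equal length makes these counts nearly equal by construction, so they do not test the imbalance.

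In 451Lu, H3K27ac that appeared only in resistant cells was found at opened rather than at closed regions. Among regions without parental H3K27ac, 5.17% of the ATAC-seq gains overlapped a resistant H3K27ac peak, against 0.890% of the losses (odds ratio 6.07, 95% counting interval 4.38 to 8.42, circular permutation p = 0.001). In WM983B, by the ATAC-seq labels, these shares were 2.42% and 1.0% (odds ratio 2.45, 1.53 to 3.92, circular permutation p = 0.001). This was not particular to resistant-only H3K27ac there. Regions with resistant-only and without parental-only H3K27ac numbered 49 among gains and 17 among losses, and those with parental-only and without resistant-only H3K27ac 55 and 24 (odds ratio 1.26, 0.606 to 2.61). The same counts in 451Lu were 562 and 37 against 7 and 74. Regions open in all 4 libraries, which were wider and scored higher, overlapped it more often than gains did. These shares were 10% in 451Lu (odds ratio of gains 0.491, circular permutation p = 0.001, adjusted p = 0.00133) and 5.60% in WM983B (odds ratio 0.418, circular permutation p = 0.001, adjusted p = 0.00133). The 451Lu ratio was 0.154 with 50% of the region covered, and the WM983B ratio 0.230 without WM983B resistant replicate 2.

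H3K9me3 was lost over more regions than it was gained in resistant 451Lu cells. Of 77124 regions 13643 (17.7%) were lost, 60.7 Mb in all, 2362 (3.06%) were gained, 15.8 Mb, and 20432 were called in all 4 libraries, against 469 to 1531 in the mixed pairings. The longest losses were 25.4 kb at chromosome 9, 21203801 to 21229200, and 21.4 kb at chromosome 2, 123644001 to 123665400. The longest gains were neighbours on chromosome 5, 49.6 kb at 162215401 to 162265000 and 43.8 kb at 161803201 to 161847000. The resistant lists were shorter, and their median fold over input was lower, at 1.69 and 1.83 against 2.17 and 2.20 in the parental libraries. With lists of equal length 7152 regions were lost and 4365 gained, and both stayed above the highest mixed count of 943. By the summed length of these whole regions the order then turned, with 31.9 Mb lost and 35.2 Mb gained. No base-by-base count was made with lists of equal length. Counted base by base from the full lists, 58.5 Mb were lost and 28.5 Mb gained, against 8.81 to 12.4 Mb in the mixed pairings, a smaller imbalance than that by whole regions.

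In shp150_AP1 cells 11315 of 82020 H3K9me3 regions (13.8%, 47.6 Mb) were lost and 1536 (1.87%) gained, against 541 to 2062 in the mixed pairings, so only the losses exceeded the background. Counted base by base, 60.5 Mb were lost and 13.6 Mb gained, against 8.04 to 17.5 Mb. The shp150_AP1 libraries held 11.5 M and 14.9 M ChIP reads in islands against 31.1 M and 21.8 M in vector_NT, so lower depth ran with the losses, and its part in them was not measured. The longest losses lay at chromosome 2, 109698801 to 109724600, and at chromosome 9, 21203801 to 21227800, the second inside the longest loss of resistant cells. The longest gains lay at chromosome 2, 22600401 to 22631800, and at chromosome 5, 161838801 to 161857400. With lists of equal length both counts, 6619 lost and 3281 gained, exceeded the highest mixed count of 1245.

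The H3K9me3 losses of the 2 comparisons coincided. Among 34858 regions called in all 4 control libraries, 41.6% of those lost in resistant cells were also lost in shp150_AP1 cells, against 3.95% of the others (4019 shared, 1390 expected; odds ratio 17.3, 95% counting interval 16.1 to 18.7, circular permutation p = 0.001, adjusted p = 0.00133). The odds ratio was 8.13 with 50% of the region covered. Of 4353 regions changed in both, 98.9% (98.5 to 99.1%) changed in one direction, where unrelated changes at the same control calls would give 86.0%. ChIP reads in islands were fewer in resistant (14.8 M and 13.2 M) than in parental libraries (15.7 M and 18.3 M) as well. The factor that scales ChIP over input counts was alike there, at 1.31 and 1.47 in resistant against 1.45 and 1.34 in parental libraries. Within chromosome and 5 classes each of parental and of vector_NT ChIP read density, the odds ratio of the losses was 12.2 (11.3 to 13.2). The share of islands lost differed between chromosomes: in resistant cells it was 2.14% on chromosome 20, 3.07% on chromosome 22 and 12.4% on chromosome 17, but 69.6% on chromosome 6 and 70.9% on X. In shp150_AP1 cells it was 3.40% on chromosome 20, 3.78% on chromosome 22, 48.5% on chromosome 6 and 67.1% on X.

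**Figure D3:**
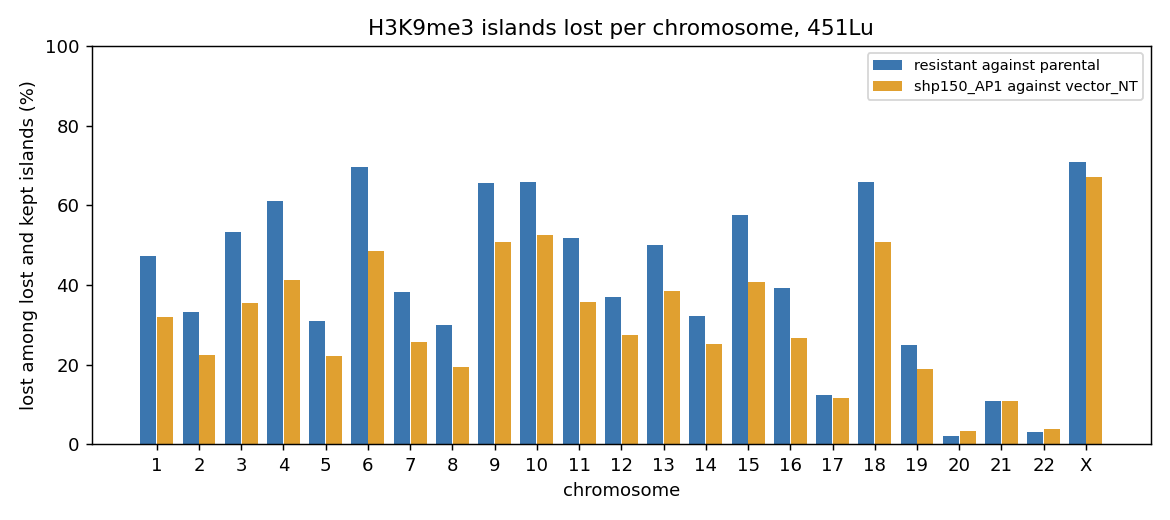
For each chromosome on the x axis, bars give the percent of H3K9me3 islands lost, out of those lost or called in all 4 libraries, in resistant (blue) and shp150_AP1 (yellow) 451Lu cells. Chromosomes 20 and 22 stand lowest, at 2.14% and 3.07% in resistant cells, and X highest, at 70.9%.

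Newly opened regions were then set against H3K9me3 losses in resistant 451Lu cells, and no difference from regions open throughout passed the test. Of the 1706 ATAC-seq gains inside parental H3K9me3 regions, 10.6% lay in a lost region, against 11.6% of regions open in all 4 libraries (odds ratio 0.896, 95% counting interval 0.753 to 1.07, circular permutation p = 0.248, adjusted p = 0.283) and 16.6% of ATAC-seq losses (odds ratio 0.594, 0.451 to 0.783, circular permutation p = 0.002). The first ratio rose above 1 without H3K9me3 parental replicate 1 (1.18, adjusted permutation p = 0.0411) or 2 (1.02). It was 0.661 with lists of equal length (adjusted permutation p = 0.008).

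The authors' deposited table gave fold changes for 1848 intervals in 451Lu, of median length 140 kb. At an adjusted p under 0.05, 614 intervals of the authors' deposited table had a positive and 762 a negative log2 fold change. The table names neither the assay nor the group that a positive value favours. Its libraries are not named either and may be among those compared here, so the associations below may not be between independent data. On chromosomes 1 to 22 and X the 613 positive intervals held 1314 regions gained and 254 lost in resistant cells (5.17 gained per lost), and the 762 negative ones 589 and 430 (1.37). The largest positive fold change in the authors' deposited table, 10.26 (standard error 0.51), was at chromosome 1, 101080000 to 101200000, which held 2 ATAC-seq gains, 4 resistant-only H3K27ac regions and 0 parental-only ones. In the same authors' deposited table, chromosome 7, 93820000 to 94060000, followed with 10.22 (standard error 0.31), and held 4 gains and 8 resistant-only H3K27ac regions. Chromosome 5, 149480000 to 149560000, had 8.71 (standard error 0.31) in the authors' deposited table, with 2 gains and 8 resistant-only H3K27ac regions. The other 7 of the 10 largest positive fold changes of the authors' deposited table lay between 7.23 and 8.66. They were on chromosomes 12 (starting at 108600000 and 47320000), 15 (36500000), 10 (48480000), 13 (38040000), 2 (188240000) and 8 (32300000).

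The largest negative fold change in the authors' deposited table, -8.53 (standard error 0.40), was at chromosome 9, 21100000 to 21220000, the interval that contains the start of the longest H3K9me3 loss named above. It held 0 ATAC-seq gains and 2 lost H3K9me3 regions. Chromosome 9, 105080000 to 105400000, had -8.18 (standard error 0.46) in the authors' deposited table, and so did chromosome 3, 155080000 to 155180000 (standard error 0.50), where 6 H3K9me3 regions were lost. The other 7 of the 10 largest negative fold changes of the authors' deposited table lay between -6.97 and -6.13, on chromosomes 6 (starting at 69000000), 4 (14360000), 5 (112940000 and 157700000), 8 (29440000), 3 (140000) and 9 (2660000). All 10 held at least 1 lost H3K9me3 region, as did 54.9% of all negative intervals, with 11 in the chromosome 6 interval.

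Intervals with a positive fold change were more often the site of newly open chromatin, in a table that may rest on the same libraries. A gained ATAC-seq region was found in 73.2% of the positive intervals (exact 95% interval 69.6 to 76.7%), 43.3% of the negative (39.8 to 46.9%) and 41.9% of those not past the threshold (37.4 to 46.5%). By Fisher's exact test, positive and negative intervals differed with an odds ratio of 3.58 (95% interval 2.85 to 4.51, p = 2.31e-29, adjusted p = 2.77e-28). It was 3.23 (2.53 to 4.12) within 5 classes of interval length, and positive intervals were longer (median 200 kb against 160 kb). Against intervals not past the threshold, which were shorter still (median 100 kb), the ratio within these classes was 1.62 (1.18 to 2.22) for positive and 0.469 (0.351 to 0.628) for negative intervals. Resistant-only H3K27ac regions were common throughout, in 89.7% of positive intervals, 71.0% of negative and 73.6% of those not past the threshold (odds ratio of positive against negative 3.57, adjusted p = 1.07e-17 by the exact test; 2.99 within the classes of length). Against intervals not past the threshold, the ratio of the positive ones within these classes was 1.29, with a 95% interval that began at 0.855 and so included 1. Parental-only H3K27ac regions went the other way, in 42.7% of positive and 67.7% of negative intervals (odds ratio 0.356, adjusted p = 6.94e-20). Gains of shp150_AP1 cells were in 47.0% of the positive and 29.9% of the negative intervals (odds ratio 2.08, adjusted p = 2.48e-10). Within the classes of length, positive intervals did not differ from those not past the threshold in these gains beyond the interval (1.17, 0.844 to 1.61).

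H3K9me3 losses were more frequent in the negative than in the positive intervals. They were found in 54.9% (exact 95% interval 51.2 to 58.4%) of negative and 41.4% (37.5 to 45.5%) of positive intervals (Fisher's exact test, odds ratio of positive against negative 0.582, adjusted p = 1.24e-06; 0.402 within 5 classes of length). H3K9me3 gains were found in 16.0% of positive and 6.69% of negative intervals (odds ratio 2.65, adjusted p = 7.46e-08). Against intervals not past the threshold and within the classes of length, the ratio of H3K9me3 gains was 1.47 (0.888 to 2.43) for positive intervals, and that of H3K9me3 losses 2.10 (1.57 to 2.80) for negative and 0.981 (0.703 to 1.37) for positive ones.

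**Figure D4:**
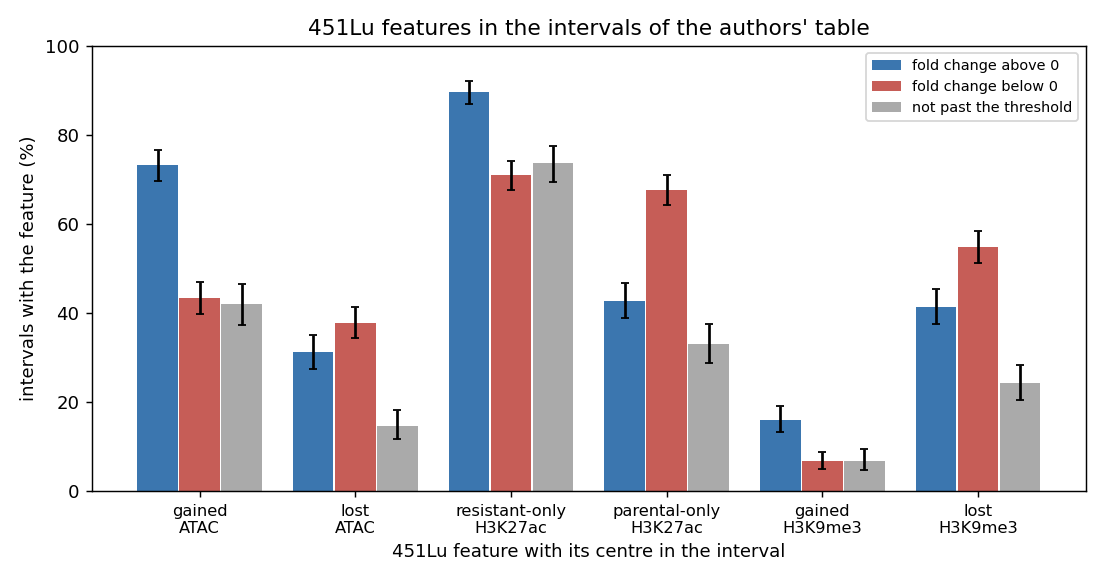
The y axis gives the percent of intervals of the authors' deposited table that hold the 451Lu feature named on the x axis, for intervals with a positive (blue) or negative (red) fold change or not past the threshold (grey), with exact 95% binomial intervals. Gained ATAC-seq regions stand at 73.2% in positive and 43.3% in negative intervals, and lost H3K9me3 regions at 41.4% and 54.9%.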

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

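The number of H3K27ac peaks moved in opposite directions in the 2 cell lines. Resistant 451Lu cells had 1.60 times as many peaks as parental cells and resistant WM983B cells 0.716 times as many. The longer list of each line also reached a lower smallest score, 1.44 in resistant against 1.89 in parental 451Lu and 1.39 in parental against 1.81 in resistant WM983B. With lists of equal length, resistant-only and parental-only regions numbered 16020 and 15803 in 451Lu and 15858 and 15972 in WM983B. That balance follows by construction from 1 list of equal length on each side and does not test the difference. With 1 library per group, the difference between the lines was not tested, and no biological explanation was tested.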

How the results depend on the processing

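The tests over the regions of all 20 ATAC-seq libraries, with islands at a false discovery rate under 0.01, on changes in one direction, with the printed interval end or 5 classes of interval length, and on the intervals with equal lists or fewer replicates were chosen after the result was seen. Of the alternative values, 167 kept their direction and side of the threshold or, for counts, lay within 1.5 times the reported value, 72 counts moved further, 17 values reversed and 3 kept their direction but passed the threshold only there. Of the 17 that reversed, 8 also passed the threshold where the reported value did not, so 11 values passed it only under an alternative, 5 passed it on both sides and 4 did not pass it. Ratios of shared gains without a treated library, which are lowered by construction, are among the 17. The share changed in one direction kept its side under each setting run (93.2 to 94.8% in ATAC-seq, 96.4 to 99.0% in H3K9me3) and without each library in turn (86.4 to 92.6% and 95.9 to 98.0%), but unrelated changes with the same control calls would give 75.8% and 86.0%, so this stability follows in part from like controls. The shared H3K9me3 losses and the interval odds ratio also kept theirs, without each library at 11.6 to 20.7 and 3.31 to 4.03. The AP-1 motif test, the gene lists, promoter-only distances and a refit of the table were not run. Sequencing depth, unknown for the peak lists, limits each count. With the replicate block, calls in both paired libraries, the 451Lu resistant gains stayed at 11191 by construction, as did the other counts. These unchanged counts are among the 167 above.

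With the better-scoring 50% of each list, counts fell because fewer peaks entered. Gained and lost regions were then 5984 and 2568 in 451Lu resistant, 1204 and 1146 in WM983B, 678 and 1124 in AP1, and 2946 and 1915 in shp150_AP1 ATAC-seq, with 2648 lost in shp150. In H3K9me3 they were 1520 and 7421 in resistant cells, with 6044 lost in shp150_AP1, and resistant-only H3K27ac regions were 14738 in 451Lu and 5559 in WM983B. With lists of equal length gained and lost regions were 1356 and 2035 in shp150, 4365 and 7152 in resistant H3K9me3 and 3281 and 6619 in shp150_AP1 H3K9me3, and 451Lu had 16020 resistant-only H3K27ac regions. With neighbours merged, 1970 were gained in WM983B, 1238 in resistant H3K9me3 and 891 in shp150_AP1 H3K9me3, where 7482 were lost. With 50% of the region covered, 3750 were gained in resistant H3K9me3.

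The odds ratio of AP1 among resistant gains was 0.550 with 50% covered, 0.560 with the better-scoring 50%, 0.363 with equal lists and 9.57 over all 20 libraries (adjusted permutation p = 0.00571, 0.0114, 0.00114 and 0.00114). That of shp150 gains was 2.24 over all 20 libraries (adjusted permutation p = 0.00267). The ratio of ATAC-seq gains within H3K9me3 losses was 1.03 with 50% covered, 1.02 with the better-scoring 50%, 0.661 with equal lists and 0.800 with the false discovery rate limit, and the last 2 passed the threshold. The cause was not tested.

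Leaving out 1 library raises counts by construction, since fewer libraries must agree on a call. Gained and lost regions then ranged from 14158 to 18682 and 6401 to 9261 in 451Lu resistant, 7282 to 22639 and 7340 to 20785 in WM983B, 2411 to 5435 and 3638 to 6849 in AP1, 1128 to 3458 and 9125 to 12459 in shp150, and 7721 to 12826 and 5613 to 9072 in shp150_AP1 ATAC-seq. In H3K9me3 they ranged from 3275 to 9342 and 17063 to 27208 in resistant and 2226 to 8376 and 15888 to 23943 in shp150_AP1 cells. The AP1 ratio ranged from 0.0683 to 1.21. It was below 1 without resistant replicate 1 (0.0683) or 2 (0.0822), AP1 replicate 1 (0.438) or 2 (0.448) or vector replicate 1 (0.974). The shp150_AP1 ratio ranged from 0.698 to 2.18. It was below 1 without resistant replicate 1 (0.791) or 2 (0.726) or shp150_AP1 replicate 1 (0.750) or 2 (0.698). Leaving out a treated library lowers the ratios of shared gains by construction, so those values do not show a reversal. Without a control library the shp150_AP1 ratio was 2.06 to 2.18. The ratio of ATAC-seq gains within H3K9me3 losses ranged from 0.869 to 1.18, turning above 1 without H3K9me3 parental replicate 1 (1.18, adjusted permutation p = 0.0411) or 2 (1.02). The WM983B ratio stayed below 1 but ranged from 0.0400 without WM983B resistant replicate 2 to 0.894 without WM983B parental replicate 2, and was 0.0557 without WM983B resistant replicate 1. The shp150 ratio fell to 0.0419 and 0.0425 without resistant replicate 1 and 2 and to 0.144 and 0.162 without shp150 replicate 1 and 2. The H3K27ac ratio at WM983B gains fell to 0.230 without WM983B resistant replicate 2.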

Other observations

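Of the tests below, only that of mixed-in cells was fixed before its result; those of copy number within chromosomes, weak sites, gains at sites prone to be called, density-matched H3K9me3 sharing, read density, change of copy number, ChIP enrichment, list length, replicate numbers, exchanged labels and WM983B H3K27ac were chosen after the result was seen.

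In WM983B, H3K27ac followed the 451Lu intervals while ATAC-seq gains by label did not exceed the mixed pairings there. Inside the intervals with a positive fold change WM983B had 1453 resistant-only and 1444 parental-only H3K27ac regions, and inside those with a negative one 739 and 2636. Intervals not past the threshold held 530 and 725, and no odds ratio was taken against these. Resistant-only and parental-only regions were found in 70.1% and 71.0% of the positive intervals, against 48.8% and 79.4% of the negative ones. The hypothesis that resistant WM983B cells change H3K27ac at the same intervals as 451Lu gave an odds ratio of 3.59 (95% bootstrap interval over intervals 3.07 to 4.16), which is consistent with it, on 1 library per group. WM983B ATAC-seq gains by label were found in 28.1% of positive and 19.9% of negative intervals (Fisher's exact test, odds ratio 1.57, adjusted p = 0.000769). Within 5 classes of interval length this ratio was 1.39 (1.07 to 1.81). Against intervals not past the threshold, that of positive intervals within these classes was 1.29 (0.887 to 1.87), which includes 1.

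Resistant and shp150_AP1 cells shared ATAC-seq and H3K9me3 changes. Among regions called in all 4 control libraries, whole-chromosome copy number as the whole cause of the shared ATAC-seq losses is argued against by an odds ratio of 28.0 (95% counting interval 25.2 to 30.99) within chromosomes. Weak sites near the calling threshold as the whole cause are argued against by 9.36 (8.41 to 10.4) within chromosome and 5 classes of control score. The fall from 28.0 leaves weak sites a part in the sharing, and regions within a class can still differ in score. Unrelated gains at sites prone to be called, as the whole cause of the shared gains, are argued against by 10.98 (10.05 to 11.99) within the number of other libraries calling a region. The fall from 22.3 without these classes leaves such sites a part in the sharing. Those other libraries were shorter 451Lu lists or WM983B lists, so proneness in the longer 451Lu lists was not held fixed. Read density and chromosome as the whole cause of the shared H3K9me3 losses are argued against by 12.2 (11.3 to 13.2) within chromosome and classes of parental and vector_NT ChIP read density. Resistant cells mixed into the shp150_AP1 libraries, or a shared subpopulation, cannot be told apart from a shared effect of the engineered changes: 59.6% of the best-scoring group of resistant gains (1 of 10 groups) was called in both shp150_AP1 libraries, between the limits set beforehand for and against mixing. A hypothesis that stays open is that the combined change may move 451Lu chromatin toward the resistant state, which was not tested against the single changes, whose controls were less like parental cells.

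The share of H3K9me3 islands lost in resistant cells varied between chromosomes, and read density, a technical explanation, may account for much of it. Over 23 chromosomes it fell with the input read density of parental islands (Spearman's rho -0.737, permutation p = 0.00013, adjusted p = 0.00032; Pearson's r -0.806, p = 1e-05, the smallest that 100000 permutations can give; r -0.691 without the 2 chromosomes farthest from the median density), 1 of 5 relations computed. Weaker ChIP enrichment in the resistant libraries also has the values it needs to go with the losses as a whole, since the median ratio of fold over input to that of parental libraries, in islands called in all 4, was 0.786 to 0.855 in the 4 pairs, though a global loss of the mark could give the same. No such ratio was taken per chromosome, so it cannot bear on the differences between chromosomes. Longer parental lists as the whole cause are argued against by the 7152 losses with lists of equal length, against at most 943 in mixed pairings. By the summed length of whole regions, though, these lists held more gain (35.2 Mb) than loss (31.9 Mb). A change of copy number between the cells cannot be told apart, as the rho of -0.0306 (permutation p = 0.891) has a bootstrap interval of -0.455 to 0.407.

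WM983B ATAC-seq regions split by replicate number (25283 regions) rather than by the labelled groups (5423), and the H3K27ac difference between parental and resistant WM983B cells followed the numbers. The odds ratio of resistant-only against parental-only H3K27ac was 30.2 for replicates 2 against 1 (95% counting interval 19.1 to 47.8; 36.4 with lists of equal length) and 1.26 (0.606 to 2.61) for the libraries labelled resistant against parental, where 451Lu gave 0.357 and 161. A batch or culture that spans both assays by number is argued against by the 30.2. Both WM983B H3K27ac libraries carry number 2, so such a batch would be common to them. The labels do not say that a number means the same batch in ATAC-seq and H3K27ac. The 30.2 therefore does not decide on a batch within ATAC-seq alone. List length as the whole cause is argued against by 23301 regions with lists of equal length, against 4909 by group. The values are consistent with exchanged labels of the ATAC-seq libraries called resistant replicate 1 and parental replicate 2, a hypothesis under which the 25283 regions may be the difference between parental and resistant cells. A bias, such as one of GC content, that differed both between the ATAC-seq numbers and between the 2 H3K27ac libraries was not tested, as no hg19 sequence was given.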
